A study of Homo sapiens with 12 samples.

How the data were processed

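RNA was measured in 12 libraries of the hepatocellular carcinoma lines Huh7 and HLF, with 2 biological replicates of each line in 2D, Inject-Embed and Mix-Embed culture, per the labels. The libraries were made from poly-A RNA and sequenced in pairs of reads on an Illumina NovaSeq instrument. FastQC, Trimmomatic, STAR 2.7.9a and featureCounts with the GRCh38 genome made the values, per the submitters' processing notes. The order and settings of these steps, the strand setting and the annotation release are not given in the sources used here. The authors deposited a table of raw counts per gene, as whole numbers, and a table of FPKM for the same genes and libraries. The deposited FPKM equal the count divided by the gene length in the table and by the library total, to within a relative 1e-06 for all 166013 values checked, which were those with at least 20 counts. The columns carry the line, a short name for the culture and a replicate number. The short name for embedded cells was read as Mix-Embed, since the other columns name 2D and Inject-Embed, and every column was assigned to a group. Nothing was left out.

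The count table held 58735 genes, 19951 of them protein-coding. Gene IDs were matched to a symbol table for 58207 genes (99.1%), and 12 gene names that had turned into spreadsheet dates were restored from their IDs. Library totals ran from 12325877 to 16041906 counts. Levels in CPM were computed from counts and the library's total over the tested genes scaled by TMM, so that 3 counts in a library correspond to 0.178 to 0.255 CPM. A ratio against a group with no counts was computed against a floor of 3 counts over the group and is given as a lower bound. With 1 to 3 counts, the ratio is given with its 95% counting interval, which covers counting error only.

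The main test was edgeR 4.0.16 with R 4.3.3, on the 12 libraries with a mean for each of the 6 groups. It used TMM scaling, the filterByExpr filter with a minimum count of 10, which left 19342 genes, and quasi-likelihood tests with Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.00211, a coefficient of variation of 4.6% between replicates, with 6 residual degrees of freedom and 36.3 prior degrees of freedom. Each 3D culture was compared with 2D and with the other 3D culture within each line. The difference between the lines was tested for each of these comparisons in the same model, and Huh7 was compared with HLF in 2D. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested genes, 47 of 49 lists. The lists were written from general knowledge before the data were examined, as were the design and the rule for the genes named, and 1059 of their 1060 members were found in the table. A count of list members that rose or fell uses the adjustment over all genes, and a second count uses an adjustment over the list alone. Principal components, overlaps and correlations were computed in R. Inputs were read with python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and the figures were drawn with matplotlib 3.10.9.

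The genes named follow a fixed rule. For each comparison within a line they are the 5 protein-coding genes with the highest and the 5 with the lowest log2 fold change among those with an adjusted p under 0.05, at least 10 CPM in the higher group and both replicates of one group above both of the other. The rule for the comparison of the lines was the same, and that for differences between the lines left out the condition on replicates. For each list called, the rule gives up to 4 members with the smallest adjusted p and up to 2 that moved the opposite way. A further set of genes was fixed, among them ALB, AFP, HNF4A, GPC3, CDH1, VIM, CD44, EPCAM, MKI67, CA9, VEGFA, HMGCS1, CYP3A4, CCN2 and COL4A1. The text gives a selection of the genes the rule names, and some of them are not reported here.

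The test was run on counts simulated from the means and totals of the real libraries, with 50 genes changed at each of 4 fold sizes. Each simulated gene took the dispersion fitted for its expression level, with no scatter of its own around that trend. The rates below therefore do not cover genes with more scatter between replicates. For Huh7 Inject-Embed against 2D, edgeR recovered 38% of the genes at the smallest size, 0.32 on the log2 scale, and 58%, 76% and 96% of those changed by 1.5-fold, 2-fold and 4-fold, and 4.3% of its calls were false. For the difference between the lines in that comparison it recovered 20%, 42%, 58% and 74% in the same order, and 0% of its calls were false. For Huh7 Inject-Embed against 2D, DESeq2 1.42.0 recovered 28%, 50%, 64% and 90%, with 2.5% false, and limma on log2(FPKM + 1) recovered 12%, 42%, 66% and 86%, with 12.7% false. Lists were also simulated for Huh7 Inject-Embed against 2D. Camera at the preset correlation, camera with an estimated correlation and fry each recovered 2 of 2 changed lists. Of 45 unchanged lists they called 0, 0 and 1. Genes were drawn independently here, so the simulation cannot show how often these tests call unchanged lists whose genes vary together.

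The alternatives tried were DESeq2, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), RLE scaling, library totals alone, no filter, a filter of at least 1 CPM in 2 libraries, protein-coding genes alone, an absolute log2 fold change of at least 1, the 6 libraries of one line, the libraries of the compared groups alone, the replicate number as a block, and each library left out in turn. The list test was also run with an estimated correlation and with fry. Correlations between the lines over genes with at least 1 CPM in both lines, and near-identical gene copies summed, were alternatives chosen after seeing the data.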

Results

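Poly-A RNA was sequenced from the human hepatocellular carcinoma lines Huh7 and HLF in 3 cultures each: a flat 2D culture, and a pair of 3D cultures in Matrigel called Inject-Embed and Mix-Embed. The labels give 2 biological replicates in each of the 6 groups, 12 libraries in all. Per the labels, the 2D cells were harvested on day 2 at about 90% confluence, and the 3D cells between day 6 and day 8. Inject-Embed started from 4000 Huh7 or 2000 HLF cells per well and Mix-Embed from 20000 or 10000, so the number of cells seeded and the days in culture differ together with the culture. The total count per library was 16041906 and 15974920 in Huh7 2D, 15556397 and 15262526 in HLF 2D, and 13836667 and 12325877 in Huh7 Inject-Embed. It was 14402603 and 14908163 in HLF Inject-Embed, 15565857 and 13852135 in Huh7 Mix-Embed, and 13521290 and 15540021 in HLF Mix-Embed. Levels below are CPM, counts over the library total scaled by TMM, given as the mean ± SD of n = 2 where an SD stands beside them. Log2 fold changes are given ± a standard error (SE) derived from the test. It is the absolute log2 fold change divided by the square root of the F statistic. Where a group holds few counts, this SE is smaller than the counting error. For MT1G in Huh7 Inject-Embed against 2D it was 0.23, beside a counting interval of 534 to 7570 on the ratio. Of 19342 genes tested, the line separated the libraries most: the first principal component, which parts Huh7 from HLF, held 91.6% of the variance. Mitochondrial ribosomal RNA, a small part of every library, took 0.31% of the counts in both Huh7 2D libraries and 0.48% to 0.54% in the Huh7 3D libraries, and 0.29% to 0.3% in HLF 2D against 0.47% to 0.6% in the HLF 3D libraries. The share of counts in protein-coding genes was 97.63% in Huh7 2D and 97.26% to 97.44% in the Huh7 3D libraries, and 97.66% in HLF 2D and 97.07% to 97.32% in the HLF 3D libraries.

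The lines in flat culture were compared first, since their starting levels set which genes can change. In 2D, Huh7 expressed the secreted proteins and transcription factors of hepatocytes, and HLF expressed mesenchymal and contractile genes. AFP, the fetal liver albumin-like protein used as a tumour marker (ENSG00000081051, chromosome 4), stood at 25000 ± 1000 CPM in Huh7 and 0.56 ± 0.44 in HLF, a log2 fold change of 15.42 ± 0.09 (adjusted p = 5.86e-58). All 28 secreted hepatocyte proteins were higher in Huh7, and 28 when adjusted over the list alone, with a median log2 fold change of 10.66, or 9.1 without the 15 members at 3 counts or fewer in a group (adjusted p = 2.78e-23). SERPINA1, a protease inhibitor of blood plasma, was at 5794 CPM in Huh7 and 1.03 in HLF. APOB, the core protein of low-density lipoprotein, had no counts in HLF and was at least 85700-fold higher in Huh7, and GPC3, a surface proteoglycan of liver tumours, at least 13100-fold higher. APOA2 and FABP1, also at 0 counts in HLF, were at least 7510-fold and 4980-fold higher. The transferrin gene TF had 1 count in HLF, a ratio of 170000 (95% counting interval 30500 to 6710000). ALB, albumin, had 3 counts in HLF, a ratio of 3810 (1300 to 18500), and HNF4A, a master regulator of hepatocyte genes, 2 counts, a ratio of 5860 (1620 to 48400).

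Of the 20 hepatocyte transcription factors, 19 were higher in Huh7 and 1 was lower (19 and 1 adjusted over the list alone, adjusted p = 2.48e-10). Among 25 epithelial junction genes, 20 were higher in Huh7 and 5 lower, with the same counts adjusted over the list alone (adjusted p = 0.000405). CDH1, E-cadherin, stood at 132 ± 5.3 CPM in Huh7 and 3.31 ± 0.39 in HLF, while KRT8, a keratin of simple epithelia, was lower in Huh7 (-2.46 ± 0.04). Of 21 mesenchymal genes, 17 were lower in Huh7 and 4 higher (17 and 4 adjusted over the list alone), with a median of -4.9, or -2.72 without 8 members at 3 counts or fewer (adjusted p = 1.6e-06). TNC and MSN, a matrix glycoprotein and a linker of actin to the membrane, had no counts in Huh7 and were at least 4870-fold and 5090-fold lower there. CBLN2, TENM3 and MAGEA4 were at least 4120-fold, 3370-fold and 2610-fold lower by the same bound. FN1, fibronectin, went the other way (6.58 ± 0.05). VIM, vimentin, was at 105 ± 7.6 CPM in Huh7 and 691 ± 23 in HLF, and CD44, a hyaluronan receptor, at 5.09 ± 0.036 and 377 ± 3.8.

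The actin and contractility list was lower in Huh7 in 21 of 24 genes and higher in 2 (21 and 2 adjusted over the list alone, adjusted p = 1.02e-06), and the list of YAP and TEAD targets in 17 of 23 and higher in 4 (17 and 4, adjusted p = 1.6e-06). Cholesterol synthesis genes were higher in 21 of 23 and lower in 2 (21 and 2 adjusted over the list alone, adjusted p = 3.86e-09). HMGCS1, an early enzyme of the pathway, stood at 1090 ± 51 CPM in Huh7 and 72.1 ± 3.6 in HLF. Wnt and beta-catenin targets were higher in 16 of 17 and lower in 1, MYC (16 and 1, adjusted p = 4.59e-06). The list of the urea cycle, amino acid catabolism and gluconeogenesis was higher in 14 of 18 genes and lower in 2 (14 and 2, adjusted p = 4.23e-05). In all, 14941 of the 19342 genes, or 77.2%, differed between the lines in 2D, 7364 higher and 7577 lower in Huh7, and 26 lists were called, 13 of them also with an estimated correlation. Calls lost with an estimated correlation included cytosolic ribosomal proteins (37 of 40 higher, adjusted p = 0.242 with an estimated correlation), antigen presentation (15 of 16 lower, adjusted p = 0.0951), mitochondrially encoded transcripts (11 of 13 higher, adjusted p = 0.0858) and the fibroblast or stellate markers (6 of 9 lower, adjusted p = 0.0793). Scaling by library totals alone moved the median of all genes to -0.18 in this comparison.

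Huh7 in Inject-Embed was compared with Huh7 in 2D to show how culture as a sphere in Matrigel changed the line that resembles hepatocytes. Metallothioneins rose from the edge of detection, cholesterol synthesis and hypoxia response genes fell, and ribosome biogenesis genes rose. MT2A, a small protein that binds zinc and copper (ENSG00000125148, chromosome 16), rose from 0.838 ± 0.24 to 240 ± 17 CPM, a log2 fold change of 8.15 ± 0.12 (adjusted p = 9.35e-40). ALB rose from 357 ± 24 to 1170 ± 57 CPM (1.71 ± 0.05, adjusted p = 7.72e-28), while AFP fell from 25000 ± 1000 to 19500 ± 810 (-0.36 ± 0.04, adjusted p = 3.65e-10). VIM fell from 105 ± 7.6 to 43.1 ± 1.7 CPM and HMGCS1 from 1090 ± 51 to 572 ± 9.2.

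Of the 15 tested metallothioneins and metal response genes, 11 rose and 2 fell, and 11 and 2 adjusted over the list alone. The median log2 fold change was 4.28, or 1.45 without the 3 members at 3 counts or fewer in a group (adjusted p = 2.53e-16). MT1E rose from 0.236 to 135 CPM (9.11 ± 0.19) and MT1M from 0.134 to 30.1 (7.73 ± 0.34). MT1G rose from 3 counts to 3916, a ratio of 1560 (534 to 7570), and MT1X from 3 to 512, a ratio of 204 (69.4 to 993). SLC30A1, a zinc exporter, rose from 21.7 to 106 CPM (2.29 ± 0.08), and the genes that fell were SLC39A10, a zinc importer (from 95.9 to 24 CPM), and TFRC, the receptor that takes up iron (-0.89 ± 0.04).

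Among 23 cholesterol synthesis genes, 19 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -0.46 (adjusted p = 2.53e-16). FDPS, which makes farnesyl diphosphate, fell from 250 to 133 CPM. PMVK rose (0.49 ± 0.12), though not without Huh7 Inject-Embed replicate 1 (0.32, adjusted p = 0.126). The fatty acid synthesis and lipid storage list fell in 15 of 21 genes and rose in 3 (16 and 3 adjusted over the list alone, adjusted p = 5.05e-11). The desaturases FADS1 and SCD fell (-1.24 ± 0.05 and -0.59 ± 0.03). DGAT2, which makes triglycerides, rose (1.07 ± 0.12). Hypoxia response genes fell in 20 of 26 and rose in 1 (20 and 1 adjusted over the list alone), with a median of -0.71 (adjusted p = 9.23e-15). P4HA1, a collagen hydroxylase, fell from 301 to 153 CPM and PFKFB4 from 94.3 to 37.8. PFKFB3, like PFKFB4 a switch of glycolysis, rose from 86.3 to 126. Glycolysis genes fell in 14 of 18 and rose in 1 (14 and 1, adjusted p = 4.92e-10), with PGK1 at -0.75 ± 0.04 and LDHA at -0.64 ± 0.04. Acute phase genes, whose products the liver releases in inflammation, fell in 10 of 12 and none rose (10 adjusted over the list alone), with a median of -1.28 (adjusted p = 1.83e-09). HP fell from 258 to 107 CPM and SOCS3, a brake on cytokine signalling, from 14 ± 2.5 to 1.81 ± 0.32.

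Ribosome biogenesis genes and MYC targets rose in 22 of 24, and 23 adjusted over the list alone, with a median of 0.46 (adjusted p = 9.24e-16). MYC itself rose from 95.6 to 186 CPM (0.96 ± 0.06). Targets of NRF2, the regulator of the response to oxidants, rose in 14 of 21 and fell in 1 (16 and 3 adjusted over the list alone, adjusted p = 2.26e-08), with NQO1 at 0.86 ± 0.06. Matrix genes fell: 11 of 18 in the basement membrane and laminin list against 1 that rose (11 and 1 adjusted over the list alone, adjusted p = 8.77e-07). So did 13 of 24 in the list of fibrillar collagens and matrix glycoproteins against 1 (13 and 1, adjusted p = 4.53e-05). COL1A2, a chain of collagen I, fell from 133 to 41 CPM, and FBLN5, an elastic fibre protein, rose from 47 to 106. Secreted hepatocyte proteins fell in 16 of 28 and rose in 5 (16 and 6 adjusted over the list alone, adjusted p = 2.17e-06), so that ALB moved against most of its list. CP, ceruloplasmin, fell from 205 to 57.9 CPM and TF from 5306 to 3408. NF-kB targets and cytokines fell in 9 of 23 and rose in 1 (9 and 1, adjusted p = 0.000833), with LIF at -2.05 ± 0.09 and ICAM1 at -2.40 ± 0.15. Unfolded protein response genes fell in 13 of 20 and rose in 2 (13 and 2, adjusted p = 0.000207). G1/S and DNA replication genes rose in 12 of 30 and fell in 2 (14 and 2, adjusted p = 0.000791), and replication-dependent histones, whose messages mostly lack a poly-A tail, rose in 7 of 16 (7, adjusted p = 0.00161). The histones rose beside a higher share of mitochondrial ribosomal RNA (0.48% and 0.49% against 0.31%) and a lower protein-coding share (97.44% against 97.63%).

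Calls of the Huh7 Inject-Embed comparison that were lost with an estimated correlation were nuclear-encoded oxidative phosphorylation (21 of 32 rose, adjusted p = 3.66e-08 with the preset and adjusted p = 0.0841 with an estimated correlation), mitochondrially encoded transcripts (7 of 13 rose and 3 fell, adjusted p = 0.0978 with an estimated correlation) and Notch (9 of 17 fell and 1 rose, adjusted p = 0.173 with an estimated correlation). The markers of cholangiocytes, the bile duct cells, rose in 6 of 9 and fell in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.00612 with the preset and adjusted p = 0.0792 with an estimated correlation). EPCAM, a surface marker of liver progenitors, rose from 50.5 ± 1.4 to 85.1 ± 8.6 CPM and KRT19 from 40.9 to 63.5. The mesenchymal list had a median of 0 and a mean of -0.44, with 5 of 21 lower and 1 higher (5 and 1 adjusted over the list alone, adjusted p = 0.0383 with the preset and adjusted p = 0.0961 with an estimated correlation). Bile acid synthesis and transport, heat shock, immediate early, angiogenic, cytochrome P450, ATF4 and lysosome lists were also called with the preset correlation alone (adjusted p from 0.0778 to 0.153 with an estimated correlation). With a library left out, calls were lost without Huh7 2D replicate 1 for the mesenchymal (adjusted p = 0.107) and bile acid lists (0.067), without Huh7 2D replicate 2 for the angiogenic (0.0807), cytochrome P450 (0.0521) and lysosome lists (0.127), and without Huh7 Inject-Embed replicate 2 for the mesenchymal (0.0726), angiogenic (0.135), ATF4 (0.0672) and lysosome lists (0.0827). In limma's test on log2(FPKM + 0.1), AFP (adjusted p = 0.449), EPCAM (0.0979) and KRT19 (0.12) were not called in this comparison. The 5 genes with the lowest log2 fold change were HAL, which breaks down histidine (-3.64 ± 0.17, from 52.8 to 4.24 CPM, adjusted p = 4.45e-21), ABLIM3 (-3.45 ± 0.22), SOCS3 (-2.95 ± 0.19), KIF5C (-2.93 ± 0.15) and MYO18B (-2.73 ± 0.34). MKI67, a marker of cycling cells (-0.03 ± 0.04, adjusted p = 0.704), and CD44 (-0.15 ± 0.16, adjusted p = 0.606) did not pass the test. In total 5777 genes were called, 2552 higher and 3225 lower, with 27 lists called by camera and 15 with an estimated correlation. The majority turned under other settings: the higher share of 44.2% became 50.7% with library totals alone. More genes were higher than lower with the 6 Huh7 libraries alone (2959 and 2837) and the compared groups alone (2772 and 2678). The lower majority also turned with limma on log2(FPKM + 1) (2783 and 2678) and on log2(FPKM + 0.1) (2593 and 2484). It stayed with RLE scaling (2544 and 3233) and DESeq2 (1892 and 2437), and of the calls with an absolute log2 fold change of at least 1, 300 were higher and 754 lower.

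Huh7 in Mix-Embed was compared with the same 2D libraries. Metallothioneins rose here too, to lower levels, whereas hypoxia and glycolysis genes rose in place of falling. MT2A reached 56.3 ± 5.4 CPM (6.05 ± 0.15, adjusted p = 1.43e-30), MT1E 27.6 and MT1F 24.6, and MT1G rose to a ratio of 239 (81.5 to 1160). Of 15 metallothionein and metal genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 2.5, or 1.2 without members at 3 counts or fewer (adjusted p = 4.9e-14). SLC30A1 rose by 1.34 ± 0.09 and SLC39A10 fell by 0.89 on the log2 scale. Hypoxia response genes rose in 15 of 26 and fell in 2 (16 and 2 adjusted over the list alone), with a median of 0.4 (adjusted p = 1.4e-12). PFKFB3 rose from 86.3 to 223 CPM, BNIP3, which removes mitochondria in low oxygen, from 242 to 436, and NDRG1 from 393 to 669. Glycolysis genes rose in 13 of 18 and fell in 1 (13 and 1, adjusted p = 4.25e-09), with ENO1 at 0.49 ± 0.04 and PGK1 at 0.51 ± 0.04. ALB rose to 661 ± 16 CPM (0.89 ± 0.05, adjusted p = 1.28e-17) and AHSG, fetuin A, from 661 to 1571, while APOB fell from 8026 to 5742.

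Bile acid synthesis and transport genes rose in 8 of 13 and none fell (10 adjusted over the list alone), with a median of 0.89 (adjusted p = 1.58e-07). ABCC2, which exports conjugated bilirubin, rose by 1.11 ± 0.06 and CYP27A1, an enzyme of bile acid synthesis, by 1.07 ± 0.07. The list of fatty acid oxidation and ketogenesis rose in 9 of 19 (10 and 1 fallen adjusted over the list alone, adjusted p = 0.0018). Unfolded protein response genes fell in 13 of 20 (14 adjusted over the list alone, adjusted p = 2.19e-09) and heat shock genes in 10 of 16 (11, adjusted p = 1.41e-06), and none of either list rose. Acute phase genes fell in 8 of 12 and rose in 1 (9 and 1, adjusted p = 6.35e-06). Lysosome and autophagy genes fell in 11 of 24 (12, adjusted p = 0.000148), and NF-kB targets fell in 6 of 23 (6, adjusted p = 0.000859), with CXCL5, which attracts neutrophils, at -1.49 ± 0.08. G1/S and DNA replication genes rose in 13 of 30 and fell in 1 (14 and 2, adjusted p = 0.000351). Cytosolic ribosomal proteins rose in 29 of 40 and none fell (35 adjusted over the list alone), with a median of 0.2 (adjusted p = 1.11e-12 with the preset and adjusted p = 0.178 with an estimated correlation).

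Other calls in Huh7 Mix-Embed were lost with an estimated correlation: secreted hepatocyte proteins (13 of 28 rose and 7 fell, adjusted p = 0.108 with an estimated correlation), and G2/M and mitosis (14 of 30 fell, adjusted p = 0.0744). Basement membrane (7 of 18 fell and 1 rose, adjusted p = 0.0669), TGF-beta targets (9 of 21 rose and 1 fell, adjusted p = 0.108), Wnt targets (7 of 17 rose and 2 fell, adjusted p = 0.0721) lost theirs too. The cholangiocyte markers (3 of 9 rose, adjusted p = 0.0728 with an estimated correlation) did as well, with EPCAM at 75.9 ± 4.5 CPM (adjusted p = 0.258 with limma on log2(FPKM + 0.1)). The cancer stem cell list was called only with the preset correlation (7 of 19 rose and 3 fell, 8 and 3 adjusted over the list alone, adjusted p = 0.0238 with the preset and adjusted p = 0.22 with an estimated correlation), and not without Huh7 2D replicate 2 (adjusted p = 0.0882) or Huh7 Mix-Embed replicate 1 (0.0541). CES1, a carboxylesterase of the liver, was among the 5 highest (3.49 ± 0.21), and KIF5C (-2.46 ± 0.14), THBS1 (-2.17 ± 0.11), ABLIM3 (-2.04 ± 0.18), CPM (the carboxypeptidase M gene, -1.84 ± 0.10) and HEPACAM2 (-1.82 ± 0.23) were the lowest. CDH1 rose from 132 ± 5.3 to 165 ± 2.3 CPM (0.32 ± 0.06, adjusted p = 0.217 with limma on log2(FPKM + 0.1)), and VIM fell to 61.2 ± 1.1. AFP fell to 23200 ± 220 CPM (-0.11 ± 0.04, adjusted p = 0.0396). That call was lost without Huh7 2D replicate 1 (-0.07, adjusted p = 0.298), Huh7 Mix-Embed replicate 1 (-0.11, 0.106) or Huh7 Mix-Embed replicate 2 (-0.10, 0.168), with protein-coding genes alone (0.0544), and with DESeq2 (0.127), limma on log2(FPKM + 1) (0.531) and limma on log2(FPKM + 0.1) (0.85). In total 4203 genes were called, 2157 higher and 2046 lower, with 24 lists called by camera and 11 with an estimated correlation. The higher share of 51.3% became 48% with library totals alone. More genes were also lower than higher with RLE scaling (1989 higher and 2196 lower), DESeq2 (1347 and 1648) and limma on log2(FPKM + 1) (1751 and 1820). With the 6 Huh7 libraries alone the numbers were 2075 and 2073. Of the calls with an absolute log2 fold change of at least 1, 397 were higher and 182 lower. Without Huh7 Mix-Embed replicate 2, 2696 genes were called.

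The 3D cultures of Huh7 were set against each other to compare the embedding methods, whose effects cannot be separated from those of the seeding number. Hypoxia and glycolysis genes were far lower in Inject-Embed than in Mix-Embed. Of 26 hypoxia genes, 21 were lower and none higher (21 adjusted over the list alone), with a median of -0.96 (adjusted p = 1.2e-37). BNIP3 stood at 139 ± 2.1 against 436 ± 14 CPM (-1.65 ± 0.05), PFKFB4 at 37.8 against 178 and VEGFA, the vascular growth factor, at 56.5 ± 6.4 against 97.7 ± 7.7. Glycolysis genes were lower in 16 of 18 (16, adjusted p = 2.55e-25), with PGK1 at 281 against 672 CPM. Cholesterol synthesis was lower in 20 of 23 (21 lower and 1 higher adjusted over the list alone, adjusted p = 9.95e-21). Fatty acid synthesis was lower in 16 of 21 with 1 higher (17 and 3, adjusted p = 7.78e-11). Ribosome biogenesis genes were higher in 19 of 24 (20, adjusted p = 1.28e-22). Heat shock genes were higher in 11 of 16 with 1 lower (11 and 1, adjusted p = 1.96e-11) and NRF2 targets in 9 of 21 with 1 lower (11 and 1, adjusted p = 3.81e-06). Metallothioneins were higher in 10 of 15 and 3 were lower (10 and 3, adjusted p = 1.93e-13), with MT2A higher by 2.10 ± 0.07 and MT1X by 2.77 ± 0.23.

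Secreted hepatocyte proteins were lower in Inject-Embed in 20 of 28 and higher in 3 (20 and 3 adjusted over the list alone, adjusted p = 3.51e-15). TF stood at 3408 against 6903 CPM and CP at 57.9 against 238, while ALB was higher (0.82 ± 0.05). Acute phase genes were lower in 7 of 12 (7, adjusted p = 0.000105) and ATF4 and amino acid response genes in 11 of 24 with 3 higher (12 and 3, adjusted p = 0.00283). Cytosolic ribosomal proteins were lower in 37 of 40 (38, adjusted p = 9.5e-16 with the preset and adjusted p = 0.17 with an estimated correlation). Hepatocyte transcription factors were lower in 8 of 20 (8, adjusted p = 0.00525 with the preset and adjusted p = 0.0882 with an estimated correlation). CDH1 was at 89.1 ± 2.5 CPM in Inject-Embed and 165 ± 2.3 in Mix-Embed (-0.89 ± 0.07, adjusted p = 3.39e-14). Besides HAL (-2.48 ± 0.19), the lowest genes included PNCK (-3.05 ± 0.22), the creatine carrier SLC6A8 (-2.79 ± 0.12) and the urea cycle enzyme ARG1 (-2.49 ± 0.13). In total 4435 genes differed, 1848 higher and 2587 lower in Inject-Embed, and 22 lists were called, 11 with an estimated correlation. The higher share of 41.7% became 52.9% when libraries were scaled by their totals alone. More genes were also higher than lower with the 6 Huh7 libraries (2296 and 2215) and the compared groups alone (2461 and 2440). The same held for limma on log2(FPKM + 1) (2118 and 2030) and on log2(FPKM + 0.1) (1962 and 1757). More stayed lower with RLE scaling (1996 and 2431) and DESeq2 (1438 and 1682). By an absolute log2 fold change of at least 1, 96 genes were higher and 583 lower.

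HLF in Inject-Embed was compared with HLF in 2D, the same comparison in the line with mesenchymal features and with the same limit. Interferon response genes rose, and contractile, YAP-target and amino acid response genes fell. Of 30 interferon response genes, 22 rose and none fell (26 adjusted over the list alone), with a median of 1.02, or 0.87 without members at 3 counts or fewer (adjusted p = 8.23e-27). IFI44L rose from 9.01 ± 1.6 to 52.9 ± 0.37 CPM (2.55 ± 0.12, adjusted p = 8.53e-22), OASL, an antiviral protein, from 0.905 to 13.5 (3.88 ± 0.25), and IFIT1, which binds viral RNA, from 14.5 to 42.2. The actin and contractility list fell in 15 of 24 and rose in 1 (17 and 1 adjusted over the list alone, adjusted p = 7.44e-16). TAGLN, transgelin, fell from 48 ± 1.9 to 5.29 ± 0.24 CPM, CALD1, caldesmon, from 28.5 to 7.88 and MYH9, non-muscle myosin, from 3946 to 2526. YAP and TEAD targets fell in 18 of 23 and rose in 1 (18 and 1, adjusted p = 8.09e-16), with IGFBP3 falling from 233 to 69.3 CPM and ANKRD1 from 28.3 to 4.57, and NT5E rising by 1.38 ± 0.07. ATF4 and amino acid response genes fell in 17 of 24 and rose in 1 (18 and 1, adjusted p = 3.35e-15), among them the amino acid carrier SLC7A5, from 205 to 74.3 CPM.

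Cholesterol synthesis genes rose in 17 of 23 HLF genes and none fell (19 adjusted over the list alone, adjusted p = 4.06e-15), with HMGCS1 rising from 72.1 ± 3.6 to 132 ± 2.8 CPM. Hypoxia genes rose in 16 of 26 and fell in 2 (16 and 2, adjusted p = 1.3e-11). PFKFB4 rose by 1.42 ± 0.09 and P4HA1 by 0.88 ± 0.06. CA9, a carbonic anhydrase of hypoxic cells, went from 1 count to 37, a ratio of 37.8 (6.37 to 1530). Glycolysis genes rose in 10 of 18 and fell in 1 (12 and 1, adjusted p = 3.28e-05). Ribosome biogenesis genes fell in 16 of 24 (19, adjusted p = 8.37e-10) and G1/S and DNA replication genes in 17 of 30 (21, adjusted p = 8.37e-10). Integrins, the receptors for matrix, rose in 12 of 18 (12, adjusted p = 5.68e-07), with ITGB8 rising from 1.28 to 7.49 CPM and ITGAV by 0.42 ± 0.05. Replication-dependent histones rose in 8 of 16 (9, adjusted p = 1.03e-05), beside a mitochondrial ribosomal RNA share of 0.47% and 0.48% against 0.29% and 0.3% and a protein-coding share of 97.28% and 97.32% against 97.66%. NF-kB targets rose in 4 of 23 and fell in 1 (5 and 1, adjusted p = 0.0025). Cell cycle inhibitors rose in 5 of 19 (9 and 1 fallen, adjusted p = 0.00147), and heat shock genes fell in 7 of 16 with 1 risen (8 and 1, adjusted p = 0.000855). TXNIP, an inhibitor of thioredoxin and glucose uptake, rose from 18.8 to 72.8 CPM.

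Antigen presentation rose in 9 of 16 HLF Inject-Embed genes (10 adjusted over the list alone, adjusted p = 4.94e-06 with the preset and adjusted p = 0.0958 with an estimated correlation). The Notch list rose in 5 of 17 and fell in 1 (6 and 1, adjusted p = 0.000606 with the preset and adjusted p = 0.166 with an estimated correlation), with its ligand JAG1 rising from 36.1 to 103 CPM and SOX9 from 15.8 to 41.9. Cytosolic ribosomal proteins fell in 10 of 40 (12, adjusted p = 0.552 with an estimated correlation and adjusted p = 0.165 without HLF 2D replicate 1), and mitochondrially encoded transcripts rose in 6 of 13 (8, adjusted p = 0.166 with an estimated correlation), beside the higher share of mitochondrial ribosomal RNA in the 3D libraries. TGF-beta targets went both ways, 9 of 21 up and 5 down (10 and 5, adjusted p = 0.239 with an estimated correlation), with ID1 at 1.44 ± 0.06. The immediate early list had a median of 0 and a mean of 0.2 (adjusted p = 0.239 with an estimated correlation), and its call was lost without HLF 2D replicate 1 (adjusted p = 0.0898), HLF 2D replicate 2 (0.0545) or HLF Inject-Embed replicate 2 (0.103). AFP rose from 0.56 ± 0.44 to 5.16 ± 0.42 CPM (3.18 ± 0.23, adjusted p = 8.01e-15), and CD44 from 377 ± 3.8 to 606 ± 10 (0.69 ± 0.05, adjusted p = 6.55e-16). SERPINE2, a thrombin inhibitor, rose from 5.34 to 78.7 CPM (3.88 ± 0.11), VCAM1, an adhesion receptor, from 11.5 to 81.2 and OLFML3 by 2.48 ± 0.21. CNN1 (-3.10 ± 0.29), TINAGL1 (-3.06 ± 0.22) and the fibrinogen gene FGB (-2.65 ± 0.06, from 166 to 26.5 CPM) fell with TAGLN and ANKRD1. In total 3471 genes were called, 1758 higher and 1713 lower, and 24 lists, 14 with an estimated correlation. The higher share of 50.6% became 63.3% with library totals alone. More genes were lower with RLE scaling (1722 higher and 1766 lower) and DESeq2 (1067 and 1249), and more were higher with limma on log2(FPKM + 1) (1827 and 1055). By an absolute log2 fold change of at least 1, 412 genes were higher and 187 lower. Leaving out any 1 of the 4 libraries gave 2247 to 2294 genes.

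HLF in Mix-Embed was compared with the same 2D libraries. Interferon response genes rose further and cell cycle genes fell. Of 30 interferon genes, 28 rose and none fell (28 adjusted over the list alone), with a median of 2.12, or 1.86 without members at 3 counts or fewer (adjusted p = 2.53e-45). IFI44L rose to 180 ± 3.3 CPM (4.32 ± 0.11, adjusted p = 1.64e-31), OAS2, which senses double-stranded RNA (ENSG00000111335, chromosome 12), from 0.25 ± 0.003 to 38.8 ± 3.1 (7.23 ± 0.27), IFI6 from 28.5 to 158 and IFITM3, which blocks viral entry, from 130 to 369. IFITM1 went from 3 counts to 361, a ratio of 122 (41.5 to 596), and XAF1, TRIM22 and OASL rose by 5.30 ± 0.33, 5.02 ± 0.45 and 4.99 ± 0.23. Antigen presentation genes rose in 14 of 16 (14, adjusted p = 1.2e-11), with B2M, a subunit of the class I complex, rising from 220 to 338 CPM. NF-kB targets rose in 12 of 23 (12, adjusted p = 3.28e-06), with CSF1, the macrophage growth factor, rising from 23.3 to 86.4 CPM and CCL5 from 1.03 to 17.9.

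The G2/M and mitosis list fell in 27 of 30 genes (28 adjusted over the list alone, adjusted p = 2.9e-15), with a median of -0.32, and the G1/S list in 27 of 30 (28 fallen and 1 risen, adjusted p = 2.9e-15), with a median of -0.4. MKI67 fell from 967 ± 46 to 808 ± 22 CPM. Actin and contractility genes fell in 21 of 24 (21, adjusted p = 2.94e-19), with TAGLN at -3.41 ± 0.16 and CNN1, calponin, at -3.84 ± 0.32. YAP and TEAD targets fell in 16 of 23 and rose in 5 (16 and 5, adjusted p = 1.64e-06), while CCN2, a target often used as its reporter, rose from 24.1 ± 0.73 to 36.5 ± 1.9 CPM. Ribosome biogenesis genes fell in 21 of 24 (21, adjusted p = 1.97e-12). ATF4 and amino acid response genes fell in 16 of 24 with 1 risen (18 and 2, adjusted p = 4.4e-12), and heat shock genes in 8 of 16 (8, adjusted p = 0.000288). Histones rose in 11 of 16 (11, adjusted p = 2.99e-08), beside a mitochondrial ribosomal RNA share of 0.58% and 0.6% against 0.29% and 0.3% and a protein-coding share of 97.07% and 97.11% against 97.66%. Hypoxia genes rose in 14 of 26 and fell in 4 (15 and 4, adjusted p = 2.48e-06). Integrins rose in 10 of 18 (10, adjusted p = 7.09e-05), and cell cycle inhibitors in 8 of 19 with 2 fallen (9 and 2, adjusted p = 0.00278). TXNIP rose from 18.8 to 234 CPM (3.64 ± 0.09) and CDKN1A, an inhibitor of cyclin-dependent kinases, from 13.4 to 28.8.

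Immediate early genes, which serum and stress switch on within minutes, rose in 9 of 22 HLF Mix-Embed genes and fell in 4 (adjusted p = 0.000333 with the preset and adjusted p = 0.0943 with an estimated correlation). EGR1 rose from 8.56 to 78.9 CPM and FOS from 1.44 to 20.7. Cytosolic ribosomal proteins fell in 32 of 40 (35 adjusted over the list alone, adjusted p = 0.21 with an estimated correlation), oxidative phosphorylation in 14 of 32 (14, adjusted p = 0.214 with an estimated correlation), and mitochondrially encoded transcripts rose in 9 of 13 and fell in 2 (9 and 2, adjusted p = 0.25 with an estimated correlation and adjusted p = 0.0528 without HLF Mix-Embed replicate 2). NRF2 targets had a median of -0.09 and a mean of 0.12, and the test gave a lower list (4 of 21 risen and 6 fallen, adjusted p = 0.0297 with the preset and adjusted p = 0.107 with an estimated correlation). AFP rose to 8.38 ± 1.9 CPM (3.86 ± 0.21, adjusted p = 1.31e-19) and CD44 to 616 ± 17 (0.71 ± 0.05, adjusted p = 1.12e-16). CCN5 (-2.37 ± 0.19), ANKRD1 (-2.20 ± 0.17) and ANKRD2 (-2.05 ± 0.26) were among the 5 lowest. In total 5605 genes were called, 2789 higher and 2816 lower, and 23 lists, 14 with an estimated correlation. The higher share of 49.8% became 62.4% with library totals alone. Of the calls with an absolute log2 fold change of at least 1, 919 were higher and 223 lower.

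The 3D cultures of HLF differed from each other in fewer genes, 1600, of which 689 were higher and 911 lower in Inject-Embed. The higher share of 43.1% became 34.6% with library totals alone, and 30 genes were higher and 144 lower by an absolute log2 fold change of at least 1. Leaving out any 1 of the 4 libraries gave 766 to 1046 genes, DESeq2 1011, and limma 982 on log2(FPKM + 1) and 670 on log2(FPKM + 0.1). Interferon response genes were lower in 27 of 30 and none was higher (28 adjusted over the list alone), with a median of -0.98 (adjusted p = 3.49e-69). IFI6 stood at 51.9 against 158 CPM and BST2, which tethers virus particles, at 4.47 ± 0.38 against 25.6 ± 0.2. IFITM1, XAF1, OAS2 and TRIM22 had the other lowest log2 fold changes, from -3.53 ± 0.32 to -2.56 ± 0.34. Antigen presentation genes were lower in 10 of 16 (10, adjusted p = 1.76e-10). Cholesterol synthesis genes were higher in 16 of 23 (19 and 1 lower adjusted over the list alone, adjusted p = 3.49e-23). G2/M genes were higher in 21 of 30 (25, adjusted p = 3e-21), G1/S genes in 11 of 30 (17 and 1 lower, adjusted p = 2.46e-09), and so were ribosome biogenesis genes in 6 of 24 (9, adjusted p = 8.62e-06) and actin genes in 9 of 24 (9, adjusted p = 5.18e-07). Basement membrane genes were lower in 8 of 18 (10, adjusted p = 4.78e-08), with LAMA5, a laminin chain, at 264 against 485 CPM. The immediate early list was lower in 7 of 22 (9 and 1 higher, adjusted p = 4.96e-07), with EGR1 at -2.48 ± 0.10. Histones were lower in 5 of 16 (7, adjusted p = 8.62e-06), beside a lower mitochondrial ribosomal RNA share (0.47% and 0.48% against 0.58% and 0.6%). NF-kB targets were lower in 6 of 23 (6, adjusted p = 2.15e-05). Lysosome genes were lower in 5 of 24 (9, adjusted p = 0.000288) and secreted hepatocyte proteins in 7 of 28 (7 and 1 higher, adjusted p = 0.000216). Hypoxia genes, unlike in Huh7, were not called, with 4 of 26 higher and 3 lower, a median of 0.01 and an adjusted p = 0.369.

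Calls between the HLF 3D cultures that were lost with an estimated correlation included cytosolic ribosomal proteins (20 of 40 higher, adjusted p = 0.145 with an estimated correlation), oxidative phosphorylation (10 of 32 higher, adjusted p = 0.0715) and YAP targets (5 of 23 lower, adjusted p = 0.0516), while CCN2 was lower in Inject-Embed (-0.78 ± 0.11). The p53 target list was called with the preset correlation alone (1 of 21 higher and 4 lower, adjusted p = 0.0234 with the preset, adjusted p = 0.0783 with an estimated correlation and adjusted p = 0.0773 without HLF Mix-Embed replicate 2). SHISA2 (0.85 ± 0.06, from 120 to 216 CPM), NPAS2 (0.85 ± 0.15) and PADI3 (0.78 ± 0.11) were among the 5 highest. The other members of the 5, U2AF1L5 (2.03 ± 0.45) and SSX2 (1.97 ± 0.20), share reads with near-identical copies, and with the copies summed the log2 fold changes were 0.86 (adjusted p = 0.14) and 0.07 (adjusted p = 0.921). Without HLF Inject-Embed replicate 2, that of U2AF1L5 alone was 0.27 (adjusted p = 0.866), and its call was also lost without HLF Mix-Embed replicate 2 (1.92, adjusted p = 0.0616) and with DESeq2 (adjusted p = 0.214), limma on log2(FPKM + 1) (0.459) and on log2(FPKM + 0.1) (0.442). In all 24 lists were called, 13 with an estimated correlation.

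**Figure D1:**
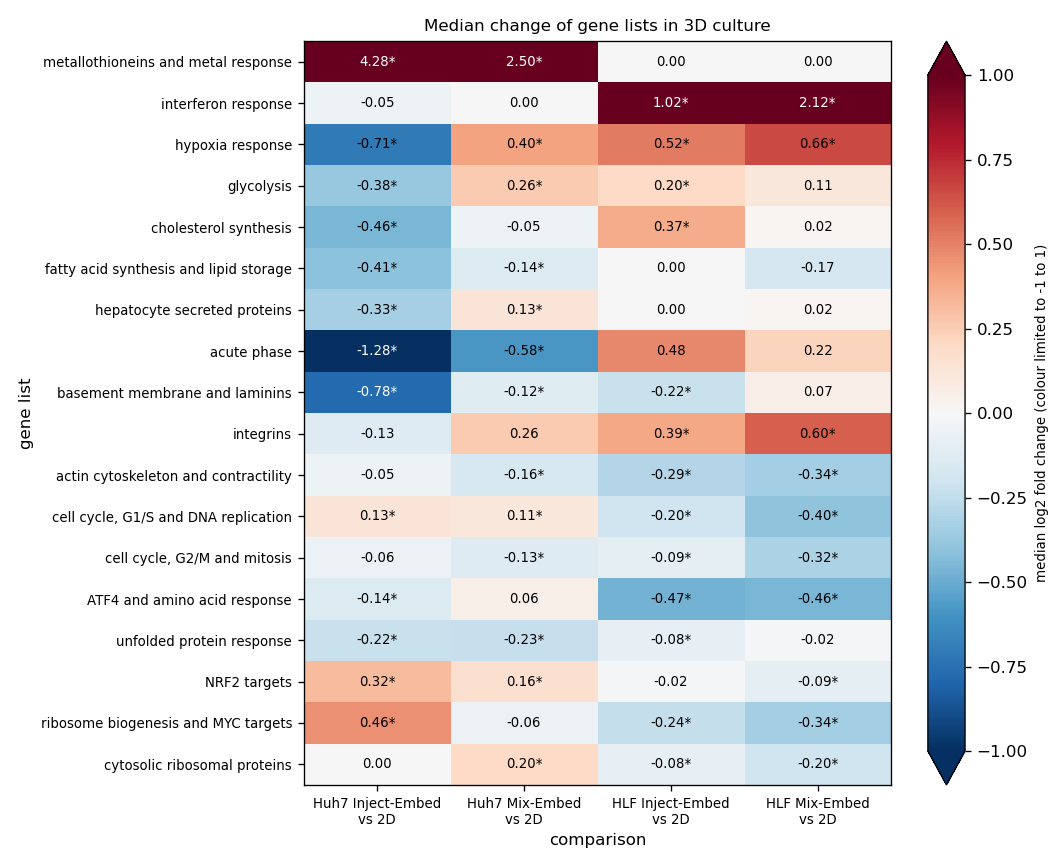
Median log2 fold change of 18 gene lists (vertical axis) in each 3D culture against 2D of the same line (horizontal axis), as colour limited to the range from -1 to 1; a star marks a camera adjusted p under 0.05. Hypoxia response is -0.71 in Huh7 Inject-Embed and 0.4 in Huh7 Mix-Embed, and interferon response is 1.02 and 2.12 in the HLF 3D cultures.

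The changes of the lines were then compared with each other, as the difference between their log2 fold changes (Huh7 minus HLF) in a single model. For Inject-Embed against 2D, 4796 genes changed differently, 2265 more upward and 2531 more downward in Huh7, with 22 lists called and 16 of them with an estimated correlation. Cholesterol synthesis genes had a lower change in Huh7 in 19 of 23 (19 adjusted over the list alone), with a median difference of -0.77 (adjusted p = 8.25e-23), and hypoxia genes in 17 of 26 with 1 higher (adjusted p = 7.77e-19), a median of -1.1. Ribosome biogenesis genes had a higher change in Huh7 in 21 of 24 (22, adjusted p = 2.86e-22), as did G1/S genes in 19 of 30 (21, adjusted p = 1.74e-10). HMGCS1 differed by -1.79 ± 0.07, VIM by -1.41 ± 0.08 and MT2A by 8.26 ± 0.15. The call for YAP targets stood at the threshold with an estimated correlation (adjusted p = 0.05 when rounded), and those for immediate early (adjusted p = 0.0689), actin (0.0968) and antigen presentation genes (0.272) were lost.

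For Mix-Embed against 2D, 3944 genes changed differently, 1968 more upward and 1976 more downward in Huh7. The upward share of 49.9% became 37.1% with library totals alone. G1/S genes had a higher change in Huh7 in 27 of 30 (28 adjusted over the list alone, adjusted p = 3.17e-22), ATF4 genes in 15 of 24 (18, adjusted p = 3.03e-14), and interferon genes a lower change in 20 of 30 with 1 higher, a median of -2.14, or -1.68 without members at 3 counts or fewer (adjusted p = 4.99e-15). Cytosolic ribosomal proteins had a higher change in 36 of 40 (adjusted p = 2.99e-27 with the preset and adjusted p = 0.0841 with an estimated correlation). For Inject-Embed against Mix-Embed, 2044 genes differed, 893 upward and 1151 downward, a share of 43.7% upward that became 61.2% with library totals alone. More were also upward with the compared groups alone (1270 and 1027) and with limma on log2(FPKM + 1) (1139 and 967). RLE scaling (962 and 1091) and DESeq2 (661 and 777) kept more downward. Hypoxia genes had a lower change in Huh7 in 19 of 26, with a median of -1.04 (adjusted p = 1.26e-43), and cholesterol synthesis genes in 20 of 23 (21 adjusted over the list alone, adjusted p = 9.34e-42). The Mix-Embed comparison called 22 lists, 12 with an estimated correlation, and the Inject-Embed against Mix-Embed comparison 17, 10 with an estimated correlation. The list of matrix proteases and inhibitors and that of ABC and multidrug transporters were called in none of the 10 comparisons (camera; smallest adjusted p = 0.0666 and 0.0643). Endothelial and blood markers were not tested as lists, with 4 and 3 genes passing the count filter.

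**Figure D2:**
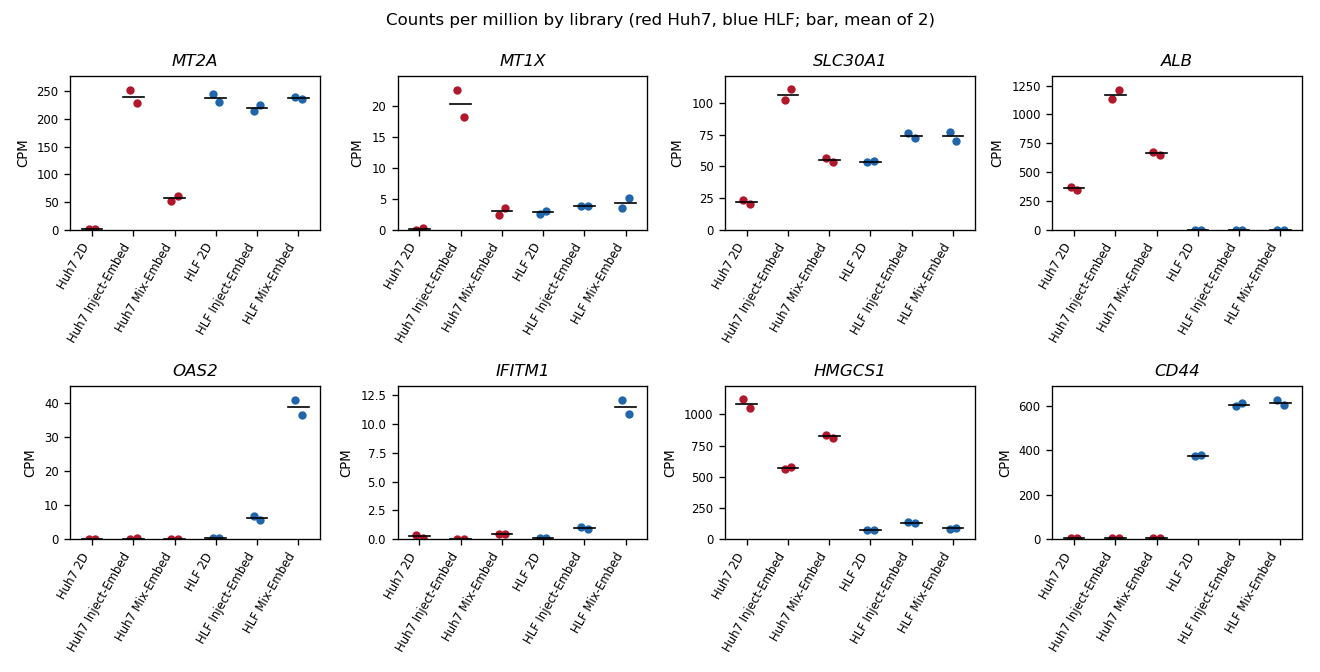
Level of 8 genes in each of the 12 libraries, in CPM on a linear axis from 0, by line and culture. Points are libraries and bars are means of 2. MT2A is near 1 CPM in Huh7 2D and at 240 in Huh7 Inject-Embed, and OAS2 rises from 0.25 CPM in HLF 2D to 38.8 in HLF Mix-Embed.

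Both 3D cultures were compared with the same 2D libraries, which links their changes. In Huh7, 1053 genes rose and 1298 fell in both, 2351 in all, against 285 and 341 for independent lists, and 242 were called in opposite directions. In HLF, 1457 rose and 1374 fell in both, 2831 in all, against 253 and 249 for independent lists, and 14 in opposite directions. Unchanged groups simulated against the same 2D libraries gave 0 shared calls in either line. With no gene changed, few calls can pass the adjustment in the first place. That count therefore cannot show how much the shared controls add to the overlap when many genes change. Across genes, the log2 fold changes of the 3D cultures correlated with r = 0.54 in Huh7 (simulated 0.48) and r = 0.668 in HLF (simulated 0.49). The covariance was 0.344 against a simulated 0.0348 in Huh7, a difference of 0.309, and 0.453 against 0.0361 in HLF, a difference of 0.417. The simulated values came from fits of the 6 libraries of one line, with the count filter applied to those libraries. The observed values used the fit of all 12 libraries and its 19342 genes, including genes kept only through the other line. Observed and simulated values are therefore not like for like, and their differences do not measure the effect of shared controls. Part of the excess of shared calls may come from the shared controls, which were not split because each part would hold 1 library. Between the lines, whose libraries are separate, the correlation across genes was r = -0.009 for Inject-Embed against 2D, 0.062 for Mix-Embed against 2D and 0.066 for Inject-Embed against Mix-Embed, and genes are not independent replicates. Of the genes called in both lines, 587 of 1639 (35.8%), 1154 of 1838 (62.8%) and 516 of 715 (72.2%) had the same sign in these comparisons.

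Genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and lists by limma's camera with a preset correlation of 0.01. With 2 replicates per group, the p values set each difference against the spread between replicate cultures of this experiment. That spread was pooled over the 6 groups and moderated across genes, with 6 residual and 36.3 prior degrees of freedom. In a test on simulated data for Huh7 Inject-Embed against 2D, 38% of genes changed by 0.32 on the log2 scale, 58% of those changed by 1.5-fold and 96% of those changed by 4-fold were recovered. The simulated genes had no scatter around the dispersion trend, so genes with more scatter between replicates are not covered. Intervals on ratios cover counting error only.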

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

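Of the tests below, the matched random lists for the interferon response were set before their result was seen, while the tests of summed metallothioneins, HLF RNA, metal ions, interferon gene counts and AFP carry-over were chosen only after the result was seen. Each value listed here was marked by a test of the difference between the lines in the same change of culture, as Huh7 minus HLF on the log2 scale. Such a difference passed the test for 4796 genes and 22 lists in Inject-Embed against 2D, for 3944 genes and 22 lists in Mix-Embed against 2D, and for 2044 genes and 17 lists in Inject-Embed against Mix-Embed. The single genes follow the rule for named genes, and the lists are those also called with an estimated correlation.

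Metallothionein genes rose in both 3D cultures of Huh7 and not in HLF, where the differences were 9.06 for MT1E, 8.26 for MT2A and 7.09 for MT1X in Inject-Embed and 6.81 for MT1E and 6.05 for MT2A in Mix-Embed (list medians 4.28 and 2.5, or 0.94 and 0.6 without the members at 3 counts or fewer in a group). Reads shared between the copies are argued against by their sum, which rose in Huh7 from 2.62 ± 0.87 to 684 ± 3.4 and 146 ± 5.4 CPM, the smaller log2 fold change being 5.8, and stood at 296 ± 17, 281 ± 10 and 299 ± 4.5 in HLF in 2D, Inject-Embed and Mix-Embed. RNA of HLF cells is argued against by 31 genes abundant in HLF and near 0 in Huh7 2D, whose median share of the HLF level in Huh7 Inject-Embed was 0% and highest 0.186%, where the sum would need 230%. SLC30A1 and SLC39A10 belong to the called list and were chosen after its result was seen, so they are not independent support for a cause. A response to zinc or another metal ion is a candidate explanation, since the exporter SLC30A1 rose by 2.29 and 1.34 and the importer SLC39A10 fell by 2.00 and 0.89 in the 3D cultures of Huh7. It stays open, since SLC30A1 also rose in HLF, by 0.47 and 0.45 (adjusted p = 3.47e-06 and 3.39e-06), where the metallothionein sum did not pass the test, though by less than in Huh7 (difference 1.82 and 0.89), and the metal content of medium and Matrigel is not given in the sources used here.

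Interferon response genes rose in both 3D cultures of HLF, and the median difference between the lines was -1.12 in Inject-Embed and -2.14 in Mix-Embed against 2D (-1 and -1.68 without the members at 3 counts or fewer), and 0.72 between the 3D cultures. A trend with gene length or expression level is argued against by random lists matched on both: the 99th percentile of their medians was 0.12 in HLF Mix-Embed against 2D, where the interferon list had 2.12, and 0 of 10000 reached it. Interferon made by the HLF cells cannot be told apart from another trigger, because the counts are too few: all 22 interferon genes together had 22 counts in 2D, 24 in Inject-Embed and 26 in Mix-Embed, with a 95% interval of 0.683 to 2.32 on the ratio of shares of Mix-Embed to 2D (exact binomial p = 0.472). Most of these counts were of IFNE (21, 22 and 17), and IFNL1, singled out after its values were seen, had 1, 0 and 9. A response to the culture itself, to its density or to the days in it may account for the pattern and was not tested.

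AFP rose in both 3D cultures of HLF and fell in those of Huh7, by 0.36 in Inject-Embed and 0.11 in Mix-Embed, the latter a call lost without Huh7 2D replicate 1 (adjusted p = 0.298) or either Mix-Embed replicate (0.106 and 0.168), with line differences of -3.54 in Inject-Embed, -3.97 in Mix-Embed and 0.43 between the 3D cultures. Huh7 RNA or reads in the HLF libraries would have to amount to 0.0337% of the Huh7 level to give the AFP of HLF Mix-Embed. At that share, 11 other genes near 0 in HLF 2D would bring 255 counts, and 35 were seen (95% interval 24.4 to 48.7), with 1 of 67.5 for TF and 0 of 56.2 for APOB but 22 of 6.39 for MTTP, which argues against carry-over as the whole source. Earlier forms of this test, the median share over 50 genes (0.017%) and over the 11 genes (0.0035%), did not exclude it, and the final form was set after they were seen. A rise of AFP in HLF itself may remain, as a hypothesis that these libraries raised and cannot test independently.

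In Inject-Embed against 2D the other genes marked were LZTS1 (6.06), ALB (5.3), PTPRO (-6.16), SNAP25 (-6.07), HPN (-5.74), TMEM47 (-5.55), APOBEC3G (-5.22) and CA9 (-5.94), where a group held 3 counts or fewer and the value depends on the prior count, as it does for MT1X. Others were CDH1 (0.91, but -0.14 with limma on log2(FPKM + 1)), VIM (-1.41), CD44 (-0.83), MKI67 (0.16), VEGFA (-0.97) and HMGCS1 (-1.79). List medians were -1.10 for hypoxia response, -0.47 for glycolysis, -0.77 for cholesterol synthesis, -0.35 for fatty acid synthesis and lipid storage, -0.32 for fibrillar collagens and matrix glycoproteins, -0.50 for basement membrane and laminins and -0.60 for integrins. They were 0.34 for G1/S and DNA replication, 0.31 for YAP and TEAD targets, 0.19 for ATF4 and amino acid response, 0.38 for heat shock, 0.41 for NRF2 targets, 0.66 for ribosome biogenesis and -1.12 for NF-kB targets and cytokines, the last -0.81 without the members at 3 counts or fewer.

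In Mix-Embed against 2D the other genes marked were SLC13A5 (5.17), PDE6B (5.07, but -0.14 with limma on log2(FPKM + 1)), UPRT (4.94), SPP1 (-6.26), IFITM1 (-6.11), OASL (-5.73) and ANXA13 (-5.66, but 0.45 with the same test), again with 3 counts or fewer in a group, and TRIM22 (-5.85), with 4. Others were CDH1 (0.85), VIM (-0.60), CD44 (-1.28), VEGFA (-0.31), HMGCS1 (-0.68) and CCN2 (-0.76). List medians were -0.53 for basement membrane and laminins, -0.28 for integrins, 0.31 for actin and contractility, 0.46 for G1/S and DNA replication, -0.19 for the unfolded protein response, 0.52 for ATF4 and amino acid response, 0.33 for NRF2 targets, 0.26 for ribosome biogenesis, -0.35 for lysosome and autophagy and -1.38 for NF-kB targets and cytokines, the last -0.80 without the members at 3 counts or fewer.

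In Inject-Embed against Mix-Embed the genes marked were OAS2 (6.95), SPP1 (6.04), TMEM52B (5.1), CTNND2 (4.21), OASL (3.57), TMEM47 (-5.41), SCRN1 (-3.4), ZFP28 (-3.28) and PDGFB (-3.24), each with 3 counts or fewer in a group. Others were VIM (-0.80), VEGFA (-0.66), HMGCS1 (-1.11) and CCN2 (0.79). List medians were -1.04 for hypoxia response, -0.76 for glycolysis, -0.67 for cholesterol synthesis, -0.37 for fatty acid synthesis and lipid storage, -0.16 for G1/S and DNA replication, -0.27 for ATF4 and amino acid response, 0.33 for heat shock, 0.38 for ribosome biogenesis and 0.71 for replication-dependent histones, whose messages mostly lack a poly-A tail and whose libraries held 0.48% and 0.49% against 0.5% and 0.54% mitochondrial ribosomal RNA in Huh7 and 0.47% and 0.48% against 0.58% and 0.6% in HLF.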

How the results depend on the processing

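The correlation between the lines over genes with at least 1 CPM in both, and summed copies, were alternatives chosen only after the result was seen. With an absolute log2 fold change of at least 1, which asks more of each gene, the genes called fell to 1054 in Huh7 Inject-Embed against 2D, 579 in Huh7 Mix-Embed against 2D, 679 between the Huh7 3D cultures, 599, 1142 and 174 in the same comparisons of HLF, 1276, 978 and 420 for the line differences in that order, and 9329 for Huh7 against HLF. Lists called with an estimated correlation numbered 15, 11, 11, 14, 14, 13, 16, 12, 10 and 13 in the same order, and fry called 38, 36, 39, 34, 41, 34, 39, 33, 27 and 44. Between the HLF 3D cultures 1600 genes became 1011 with DESeq2, 982 with limma on log2(FPKM + 1) and 670 on log2(FPKM + 0.1), and the cause was not tested. The correlation between the lines for Inject-Embed against 2D was -0.009 and became 0.007 with a filter of at least 1 CPM in 2 libraries. Over genes with at least 1 CPM in both lines it was -0.058, and 0.121 and 0.189 for Mix-Embed against 2D and Inject-Embed against Mix-Embed. The direction of line differences turned with limma on log2(FPKM + 1), where a pseudocount of 1 weighs on low genes: CDH1 -0.14 and EPCAM 0.48 in Inject-Embed against 2D, PDE6B -0.14, ANXA13 0.45 and EPCAM 0.49 in Mix-Embed against 2D, and CDH1 -0.58 between the 3D cultures. Leaving out each library in turn, with the lone sample assumed to vary like the other groups, so fewer samples, gave 2247 to 2294 genes in HLF Inject-Embed against 2D and 766 to 1046 between the HLF 3D cultures, lower whichever library was left out. Huh7 Mix-Embed against 2D gave 2696 (without Huh7 Mix-Embed replicate 2) to 3764. The correlation of the 3D changes ranged from 0.448 to 0.649 in Huh7 and from 0.538 to 0.75 in HLF. It rose from 0.54 to 0.645 and 0.649 without a 2D library of Huh7, and from 0.668 to 0.75 and 0.749 without one of HLF. Without any 3D library it fell. More noise in the shared 2D libraries could raise it in this way, so part of the correlation may come from those libraries. Other counts moved by no more than 1.5 times, and the causes of the shifts in the list counts and correlations were not tested. The labels do not say whether replicates of the same number share a culture or a day. The differences between replicates 1 and 2 correlated between groups with r from -0.126 to 0.09. A replicate block moved no count by over 1.5 times (5675 against 5777 genes in Huh7 Inject-Embed against 2D). Of the 1292 values of named genes, 1292 kept their direction and side of the threshold with RLE scaling, 1284 with the block and 1268 with library totals alone. DESeq2 kept 1239, limma on log2(FPKM + 1) 1191 (88 lost the call, 6 turned) and on log2(FPKM + 0.1) 1162 (125 lost it). Apart from the fixed set, these genes were chosen for extreme fold changes or small adjusted p in the main fit. The counts therefore do not measure how stable calls are in general. Leaving out each library in turn, the call was lost in 345 combinations of a value and a library, and gained in 6. Depth limits genes near 3 counts, 0.178 to 0.255 CPM in a library, where fitted folds depend on the prior count.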

Other observations

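Of the tests below, that of ribosomal proteins was set before its result was seen, and that of hypoxia and seeding was chosen only after the result was seen. In HLF Mix-Embed against 2D, genes of the Notch pathway, by which neighbouring cells signal through contact, rose in 6 of 17 and none fell, 6 and 1 adjusted over the list alone (adjusted p = 0.00101 with the preset and adjusted p = 0.199 with an estimated correlation). JAG1, a ligand, rose from 36.1 to 133 CPM (1.88 ± 0.06), LFNG, which modifies the receptors, from 119 to 249, NOTCH2 from 697 to 942 and HES1, a direct target, from 0.563 to 3 CPM (2.39 ± 0.33). Fibrillar collagens and matrix glycoproteins rose in 11 of 24 genes and fell in 4 (13 and 4 adjusted over the list alone, adjusted p = 0.0297 with the preset and adjusted p = 0.0986 with an estimated correlation). COL6A2 rose from 201 to 346 CPM, FN1 from 52.4 to 77.5 and COL6A1 from 106 to 159, while COL1A1 fell from 91.1 to 54.1 and TGFBI from 66.8 to 29.6. The list of cytochrome P450 and conjugation enzymes rose in 6 of 20 (6, adjusted p = 0.0416 with the preset and adjusted p = 0.117 with an estimated correlation), with CYP1B1 from 71.6 to 123 CPM and UGT2B7 from 7.46 to 15.4. Both of these last calls were lost without HLF 2D replicate 1 (adjusted p = 0.0885 for the matrix list and 0.0549 for the enzymes), and one each without HLF Mix-Embed replicate 2 (0.0542, matrix) and without HLF Mix-Embed replicate 1 (0.0982, enzymes).

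In HLF Inject-Embed against 2D, the fetal liver and progenitor list rose in 5 of 18 genes and fell in 2 (5 and 2 adjusted over the list alone, adjusted p = 0.0461 with the preset and adjusted p = 0.138 with an estimated correlation). CD24 rose from 704 to 963 CPM and SPP1, osteopontin, from 22.3 to 54.2, while LIN28B and IGF2BP1, RNA-binding proteins of fetal tissue, fell from 80.2 to 54.4 and from 287 to 223. EPCAM had 3 counts in HLF 2D and 19 in Inject-Embed, a ratio of 6.46 (1.9 to 34.1). Its call was lost without HLF 2D replicate 2 (adjusted p = 0.204), without HLF Inject-Embed replicate 1 (0.241) and with limma on log2(FPKM + 1) (0.0992). The call of the list was lost when any 1 of the 4 libraries compared was left out (adjusted p from 0.0593 to 0.0873). CDH1 fell from 3.31 ± 0.39 to 1.18 ± 0.29 CPM (-1.48 ± 0.25, adjusted p = 1.7e-05), and COL4A1 from 350 ± 3.9 to 288 ± 0.038 (adjusted p = 6.36e-05). Between the 3D cultures of Huh7, Notch genes were lower in Inject-Embed in 7 of 17 and higher in 1, JAG1 (9 and 1 adjusted over the list alone, adjusted p = 0.00228 with the preset and adjusted p = 0.212 with an estimated correlation), with NOTCH3 at 23.1 against 48.1 CPM and HEY1 at 15.6 against 32.9. In Huh7, HNF4A rose from 366 ± 9.8 CPM to 498 ± 21 in Inject-Embed and 550 ± 13 in Mix-Embed, and GPC3 fell from 1224 ± 17 to 828 ± 20 and 978 ± 18. CYP3A4 did not pass the count filter.

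Hypoxia response genes fell in Huh7 Inject-Embed and rose in Huh7 Mix-Embed. A candidate explanation is that more cells seeded per well in Mix-Embed raise the hypoxia response in either line, which would make the list lower in Inject-Embed than in Mix-Embed. In HLF, where the seeding differed by the same factor, the median log2 fold change of the list was 0.01 (adjusted p = 0.369), which argues against an effect of that size in both lines. An effect of seeding or of aggregate size in Huh7 alone stays open, since the number of cells seeded goes with the culture.

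Cytosolic ribosomal proteins rose in Huh7 Mix-Embed, and their genes are short and abundant, so a trend with gene length or expression level could give the same shift. Random lists matched on both had a 99th percentile of their medians of 0.11, below the 0.2 of the list, and 1 of 10000 reached it. Ribosomal protein genes were left out of the matching pool, and how close the matches came was not measured. Members were drawn independently, so correlation between genes is not in these values. They argue against such a trend as the whole cause only as far as the matches are close. The list's call was lost with an estimated correlation (adjusted p = 0.178), so the shift is left as a hypothesis.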
